A study of Danio rerio with 6 samples.

How the data were processed

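The study profiled gene expression in the proximal tubule of the zebrafish pronephros in 6 libraries, 3 from wild-type and 3 from Hnf1b-depleted larvae. Per the labels' protocols, about 50 larvae of a line expressing EGFP in the proximal tubule were taken at 3 days post-fertilisation, kept in 10 mM dithiothreitol for 1 h and digested with 5 mg/ml collagenase I for 3 h at 32 °C, and green tubules were picked by hand. Per the labels' protocols, libraries were made with a stranded total RNA kit. Hand-picked tubules can carry cells of adjoining tissues, so markers of other cell types were measured in every library.

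The values are estimated counts per gene deposited by the authors in 1 table with a column per library. Per the submitters' processing notes, Salmon 0.8.2, FastQC, DESeq2 1.20.0 and the GRCz11 genome build were used, with no role given for each, and the annotation release is not given in the sources used here. Across the libraries 59.5% of values were not whole, and all were rounded to whole numbers before testing. The table held 30627 gene rows and no row without a gene. Salmon divides reads between similar transcripts by estimation, so genes with a near-identical copy are uncertain where their reads could be shared. How alike in sequence the SOCS3, SLC4A4, SLC16A9 and HNF1B pairs are was not measured, nor was it for the c6, keratin and solute carrier families. No genome of the build was at hand, so positions are not given.

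Library totals were 31810876, 28967218 and 31178497 estimated counts for wild-type libraries 1 to 3 and 27864875, 31720868 and 29023675 for depleted libraries 1 to 3. The samples are titled control and morpholino, and the labels do not say whether control larvae were injected. The columns name the group of each library but carry other numbers than the titles in the depleted group, so libraries are numbered here by column; every column was mapped to a group. No replicate pair was identical, and within groups the chi-square per degree of freedom over genes ran from 54.8 to 146.2, so each library counted as 1 replicate. Pearson's r of log2 CPM within groups, across genes, which are not independent replicates, ran from 0.9576 to 0.9873. Between groups it ran from 0.9406 to 0.9734. Wild-type libraries 1 and 2 had a higher r with depleted library 1 (0.9688 and 0.9734) than with wild-type library 3 (0.9576 and 0.9633). The first and second principal components held 44.2% and 22.0% of the variance.

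Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM (factors 0.915 to 1.08) and tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, all 6 libraries in one fit with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and the threshold was 0.05. The common biological coefficient of variation was 0.332. Fold changes are on the log2 scale, depleted over wild-type, with standard errors taken from the F statistic. CPM are estimated counts scaled to a common library size with TMM factors, as mean ± SD. Shares of counts use all gene rows, with 95% Wilson intervals from SciPy 1.17.1 for single libraries and, between groups, an exact permutation test over the 20 assignments, whose smallest two-sided p is 0.1.

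Gene lists were fixed before the data were examined: 32 lists of processes, nephron segments and other cell types, and 9 families defined by symbol. Of 24278 tested genes each list's members were counted as higher, lower or not past the test, over all genes and adjusted over the list alone. The 40 lists with 5 or more tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry. With the preset correlation 25 lists passed (11 higher, 14 lower), and with an estimated correlation none did: the smallest adjusted p was 0.309 and 6 lists had an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance one way, passed 8 lists: distal nephron, podocyte, matrix, p53, interferon, epidermis, ionocyte and V-ATPase. Its mixed form, which counts changes in either direction, passed 25. Symbols came from a table pairing identifiers with names, which gave a symbol to 23607 identifiers, many in human style and shared by several zebrafish genes. Of 1374 list names 1012 matched exactly, 267 matched by their stem without the zebrafish suffix, and 95 did not match.

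Genes are named by a rule fixed before the data were examined: the HNF1 family; the 10 largest and 10 smallest log2 fold changes among called genes with a symbol other than a clone name, a mean of at least 10 CPM and no overlap of groups; the 5 largest rises and 5 largest falls in CPM; up to 4 members of each list by p; and the 15 most abundant wild-type genes. Named after their values were seen were SLC34A1, SLC3A1, SLC7A9, SLC23A1, SLC20A1, slc22a21, pdzk1, SLC43A2, the second identifiers of SLC4A4, SLC16A9 and DAB2, VIL1, FN1, PDGFRA, TGFB2, MMP14, CDH11, cdkn1a, slc12a10.2 and, in the closing observations, c6.1, c7a and the other c5 to c9 genes, TP63, PTGES, ADM, RHBG, CDH17, krt8, krt18a.1 and col17a1a.

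Alternatives fixed before the data were examined were DESeq2 size factors, library totals only, TMM without the 20 most abundant genes and mitochondrial and globin genes, no filter, a stricter filter (1 CPM in 3 libraries and a mean count of 10), DESeq2 1.42.0 Wald tests, limma-voom, non-robust estimation, each library left out in turn, a test against a log2 change of 0.5 (glmTreat) and, for lists, a prior count of 0.5. The level of muscle markers as a covariate was added after the data were seen. The procedure was tested on simulated counts with the means and spread of these libraries. With 3 libraries against 3 and 23992 genes it recovered 62 of 98 genes changed by 2 on the log2 scale (63.3%) and 9 of 98 changed by 1 (9.2%), with 7 false calls, and with no gene changed it made 0 calls. With 2 libraries against 3 it recovered 40.8% and 4% of such genes. Simulated genes were drawn independently of each other, and no simulated library was set apart by other tissue. The false calls of the simulation therefore do not give the number to be found in these data. Figures were drawn with Matplotlib 3.10.9.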

Results

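RNA was sequenced from proximal tubules of zebrafish larvae, collected by hand under green fluorescence from a transgenic line that marks this segment of the pronephros, the larval kidney. There were 6 libraries in 2 groups: 3 from wild-type larvae and 3 from larvae depleted of Hnf1b, a homeodomain transcription factor of tubule epithelium. Each library was made from about 50 larvae at 3 days post-fertilisation. The library totals ran from 27864875 to 31810876 estimated counts over 30627 gene rows, and 24278 genes had enough counts to be tested. The labels do not say whether the libraries of a group came from separate clutches, so p-values measure the spread between these samples, part of which may be technical. Gene identifiers are those of the deposited table, and an identifier is added wherever several share a symbol.

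The wild-type libraries held transcripts of several tissues beside the tubule. Among the 15 most abundant genes were actc1b, myhz1.1 and atp2a1 of skeletal muscle, krt4 and krt5 of epidermis, COL2A1 (ENSDARG00000069093) of cartilage, and the heat shock genes hsp70l and hsp70.3. The gene actc1b stood at 7697 ± 4403 CPM (counts scaled to library size; SD, n = 3) and krt4 at 6345 ± 497 CPM. Muscle markers took 5.00% ± 2.58 of counts in wild-type libraries and 5.00% ± 1.14 in depleted ones (SD, n = 3 each), epidermis markers 2.48% ± 0.305 and 1.39% ± 0.0734. Tubule genes ranked lower: LRP2, the endocytic receptor megalin, stood at 209 ± 33.5 CPM and rank 614 in the wild-type libraries, the bicarbonate cotransporter SLC4A4 (ENSDARG00000013730) at 180 ± 38.3 CPM and rank 736, and the vitamin B12 receptor CUBN at 105.5 ± 31.6 CPM and rank 1428.

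**Figure D1:**
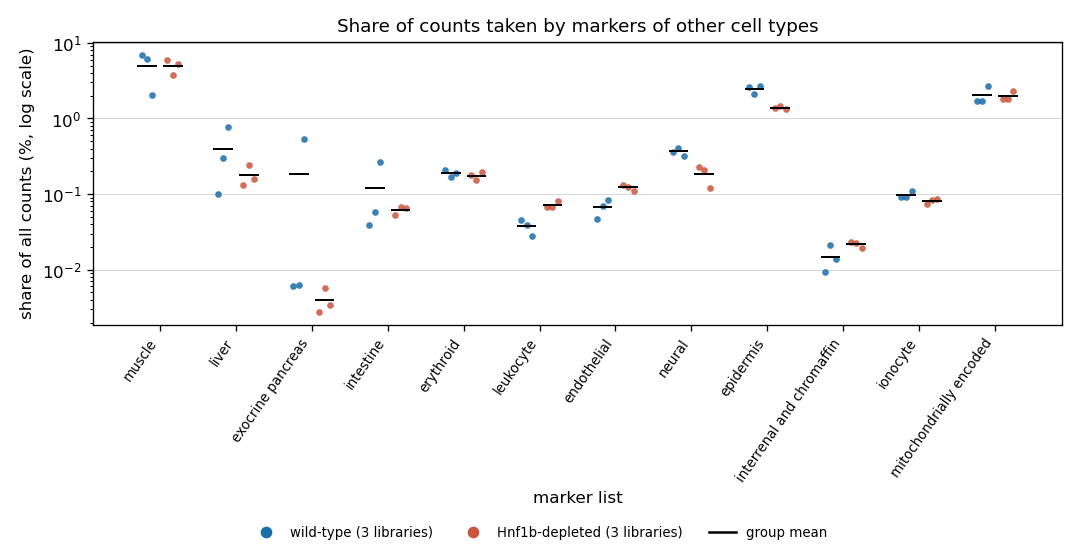
Share of all counts, in percent on a log axis, taken by each list of cell type or composition markers in the 3 wild-type and 3 Hnf1b-depleted libraries, with points for libraries and bars for group means. Wild-type library 3 held 0.537% exocrine pancreas markers, where the other 5 libraries held at most 0.00623%.

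Wild-type library 3 stood apart from the other libraries. Exocrine pancreas markers took 0.537% of its counts (95% Wilson interval 0.535 to 0.54), against 0.00615% and 0.00623% in wild-type libraries 1 and 2. Liver markers took 0.774% (0.771 to 0.777) and intestine markers 0.269% (0.267 to 0.271) in this library. The next highest library held 0.301% liver markers (wild-type library 2) and 0.0674% intestine markers (depleted library 2). Its muscle share was 2.06% (2.05 to 2.06), the lowest of all 6. These intervals cover counting error only. Across groups, endothelial markers took 0.0665% of counts in wild-type and 0.123% in depleted libraries, leukocyte markers 0.0375% and 0.0719%, neural markers 0.366% and 0.186%, and ionocyte markers 0.0977% and 0.0811%. In these 4 lists, the epidermis list and the exocrine pancreas list the libraries of one group did not overlap those of the other, for which the exact permutation test gave its smallest two-sided p of 0.1, or 0.2 after adjustment over the 12 marker lists. Erythroid markers took 0.189% and 0.175%, interrenal and chromaffin markers 0.015% and 0.0215%, and mitochondrially encoded genes 2.02% and 1.97%, with overlapping libraries.

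Of the 3 genes of the targeted HNF1 family 1 rose and 2 did not pass edgeR's test. The symbol HNF1B was shared by a pair of gene identifiers. One of them, ENSDARG00000022295, rose by 1.77 on the log2 scale (SE 0.26, edgeR adjusted p = 0.0308), from 40.6 ± 7.53 to 139 ± 43.5 CPM (SD, n = 3 each), and was higher in every depleted library than in any wild-type library. Its call was lost in each of the 6 fits without 1 library, at adjusted p of 0.0515 to 0.0936. The other, ENSDARG00000006615, stood at 56.6 ± 22.1 and 98.1 ± 7.25 CPM, a log2 difference of 0.79 (SE 0.30) with an adjusted p of 0.196. HNF1A stood at 4.93 ± 3.88 and 1.84 ± 0.292 CPM (log2 fold change -1.42, SE 0.64, adjusted p = 0.259). The depleted samples are titled as morpholino samples, and the labels do not say whether the morpholino blocks translation or splicing. A block of translation would not lower the transcript, so these levels do not check the labels.

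Between depleted and wild-type libraries 515 of 24278 genes changed past an adjusted p of 0.05 in edgeR's quasi-likelihood test, 337 higher and 178 lower, and 444 of them differed by more than 2-fold. The lower genes included CUBN, the vitamin B12 receptor, its partner amn, and the solute carriers SLC5A11 and SLC26A1. The higher genes included the matrix regulators TIMP2 (ENSDARG00000075261), THBS1 (ENSDARG00000103775) and SERPINE1 and the receptor gene TGFBR2 (ENSDARG00000059363). All 515 changed genes had groups without overlap. Chance gives this for 10% of genes, but the calls were made on the same values, so it is not separate support. Of all genes tested, 5172 had an unadjusted p under 0.05. The count rested on all 6 libraries: it was 63, 258 or 171 without wild-type library 1, 2 or 3, and 22, 34 or 12 without depleted library 1, 2 or 3. DESeq2 called 2767 genes, 1414 higher and 1353 lower, including all 515.

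More proximal tubule solute transporters fell than rose. Of 71 tested members of the list, 12 fell and 4 rose, and adjusted over the list alone 29 fell and 5 rose. The median log2 fold change was -0.89. As a sum, the list took 0.333% of counts in wild-type and 0.311% in depleted libraries, with overlapping libraries (exact permutation test p = 0.8). The sodium phosphate cotransporter SLC34A1 (ENSDARG00000028824) fell by 2.54 on the log2 scale (SE 0.31, adjusted p = 0.0208), from 41.6 ± 11.3 to 7.12 ± 2.47 CPM. The inositol carrier SLC5A11 fell by 2.63 (SE 0.29) and the sulphate carrier SLC26A1 by 2.79 (SE 0.50). The basolateral bicarbonate exit pathway was represented by SLC4A4 ENSDARG00000013730, which fell by 1.98 (SE 0.23), and by SLC4A4 ENSDARG00000044808, which fell by 1.13 (SE 0.18). Both chains of the dibasic amino acid and cystine carrier were among the lower genes, SLC3A1 by a fall of 1.05 (SE 0.18) and SLC7A9 by a fall of 2.39 (SE 0.42). The others that fell were the sodium pump subunit ATP1B1 (ENSDARG00000076833), the vitamin C carrier SLC23A1, slc22a21, the scaffold pdzk1 and pdzk1ip1. Those that rose were the monocarboxylate carrier SLC16A9, by 3.54 (SE 0.42) for ENSDARG00000013926 and 1.6 (SE 0.26) for ENSDARG00000104687, the water channel AQP1 (ENSDARG00000023713), by 1.92 (SE 0.22), and the amino acid carrier SLC43A2 (ENSDARG00000036848), by 1.28 (SE 0.16). The phosphate carrier SLC20A1 had one identifier at a log2 difference of 1.24 (ENSDARG00000010641, adjusted p = 0.0522) and another at -1.45 (ENSDARG00000020114, adjusted p = 0.192). The list passed camera with a preset correlation (adjusted p = 8.59e-07) and lost this call at adjusted p = 0.356 with an estimated correlation. It did not pass fry for a common direction (adjusted p = 0.0788) but passed fry's mixed test, for changes in either direction (adjusted p = 0.000543). Without wild-type library 3, which carried the pancreas, liver and intestine transcripts, 6 members fell and 3 rose, and the list median was -0.34 over the same 71 genes; over the 6 ways to leave out 1 library, 0 to 7 fell and 0 to 3 rose.

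Solute carriers were over-represented among the lower genes, largely through the proximal tubule transporters named above. The family made up 15 of the 154 lower genes with a symbol and 415 of the 20500 tested genes with one. The odds ratio was 5.38 (95% interval 2.91 to 9.29, two-sided Fisher's exact test p = 5.80e-07). Fisher's test takes genes as independent and leaves out the spread between libraries. Its interval is too narrow and its p too small where genes move together. Among the 15 were SLC34A1, SLC5A11, SLC26A1, both SLC4A4 identifiers, SLC3A1, SLC7A9, SLC23A1 and slc22a21 of the transporter list, so this result is not separate from that list. Another was slc12a10.2, an ionocyte marker. The glucose and mannose carrier SLC5A9 fell by 3.13 on the log2 scale (SE 0.34), from 53.7 ± 14.5 to 6.11 ± 2.21 CPM, and the glutamate carrier SLC1A2 (ENSDARG00000102453) fell by 1.54 (SE 0.27). Over the family, 15 of 415 members fell and 6 rose, among them SLC16A6 (ENSDARG00000060246) by 1.45 (SE 0.16); adjusted over the list alone 44 fell and 15 rose. Camera gave an adjusted p of 0.000276, and an adjusted p = 0.356 with an estimated correlation. Without wild-type library 3, 4 members fell and 3 rose. No solute carrier was among the 2, 12 or 1 lower genes left without depleted library 1, 2 or 3.

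Both genes of the cubilin and amnionless receptor complex fell. CUBN (ENSDARG00000087013) fell by 3.1 on the log2 scale (SE 0.28, adjusted p = 0.011), from 105.5 ± 31.6 to 12.3 ± 2.61 CPM (SD, n = 3 each), and amn, which carries cubilin to the apical surface, fell by 3.33 (SE 0.45), from 5.49 ± 1.3 to 0.536 ± 0.303 CPM. LRP2 stood at 209 ± 33.5 and 110.0 ± 10.8 CPM (log2 fold change -0.93, SE 0.18, adjusted p = 0.0524). Of the 21 endocytic genes tested, the adaptor DAB2 (ENSDARG00000053091) rose by 1.05 (SE 0.16), CUBN and amn fell, and 18 did not pass the test; adjusted over the list alone 2 rose and 3 fell, and the median was -0.04. A second identifier named dab2 (ENSDARG00000031761) stood at 78.9 ± 11.2 and 58.9 ± 9.37 CPM (log2 fold change -0.42, adjusted p = 0.236). Camera did not call a common shift of this list (adjusted p = 0.332), while fry's mixed test, for changes in either direction, did (adjusted p = 0.000658). DAB2, CUBN and amn each lost the call without some libraries: 0 to 2 members fell and none rose over the 6 ways to leave out 1 library.

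**Figure D2:**
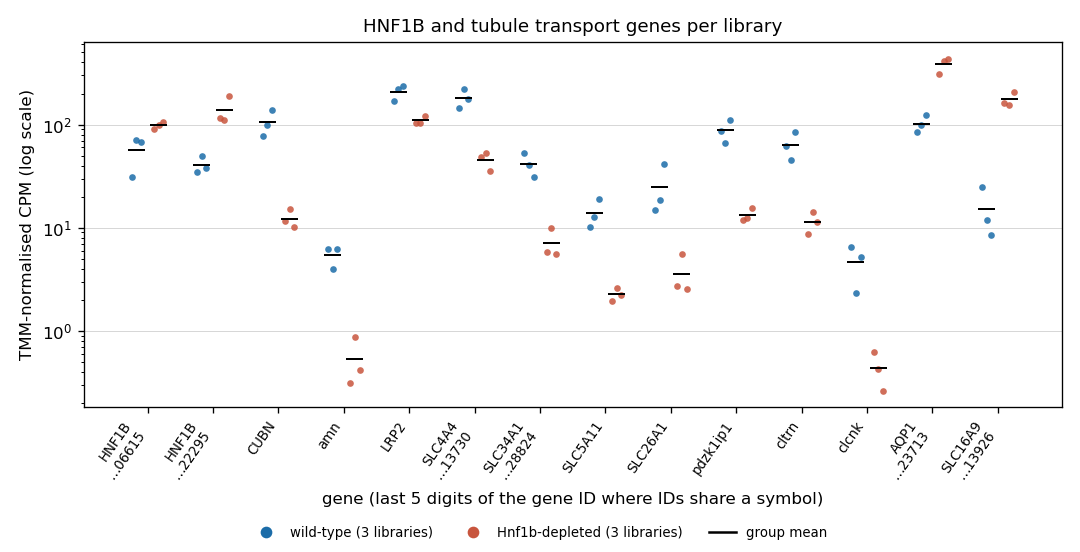
Level of each gene in TMM-normalised CPM on a log axis, with a point for each of the 3 wild-type and 3 Hnf1b-depleted libraries and a bar for the group mean. CUBN stood at 105.5 CPM in wild-type and 12.3 CPM in depleted libraries, while HNF1B ENSDARG00000022295 stood at 40.6 and 139 CPM.

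Some brush border and distal nephron genes fell too. Among 31 brush border genes, the collectrin gene cltrn, whose product carries amino acid transporters to the membrane, fell by 2.48 on the log2 scale (SE 0.29), the actin regulator eps8l3a fell by 1.42 (SE 0.26); adjusted over the list alone 5 fell. The villin gene VIL1 stood at 144 ± 196 CPM in wild-type libraries and 10.7 ± 4.90 in depleted ones (adjusted p = 0.134), a spread set by wild-type library 3. Among 37 distal nephron genes the calcium-binding pvalb8 fell by 3.09 (SE 0.40), and adjusted over the list alone 6 fell. At low levels, the chloride channel clcnk fell by 3.4 (SE 0.51), from 4.70 to 0.44 CPM. Its subunit bsnd fell by 2.15 (SE 0.37), from 1.07 to 0.24 CPM. The calls of pvalb8, clcnk and bsnd held in 2, 1 and 0 of the 6 fits without 1 library. Camera gave adjusted p = 0.000972 for the brush border list and 0.000265 for the distal list, with adjusted p = 0.629 and adjusted p = 0.309 with an estimated correlation. Ionocyte markers, 7 of which are also among the tested distal genes, were lower in the same libraries, at a share of 0.0977% in wild-type and 0.0811% in depleted libraries and a list median of -0.93. Without wild-type library 3 a single member of each list fell, over the 6 ways to leave out 1 library 0 to 1 brush border and 0 to 2 distal genes fell, and the list medians went from -0.82 to -0.23 and from -0.59 to -0.53.

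Metabolic and acidification genes of the tubule showed few single calls. In the list of gluconeogenesis and amino acid catabolism, UPB1, an enzyme of pyrimidine breakdown, fell by 2.22 on the log2 scale (SE 0.35), as the single call among 95 tested genes in edgeR; adjusted over the list alone 3 fell and 1 rose, and DESeq2 called 21 lower and 2 higher. GATM, of creatine synthesis, stood at 118 ± 32.7 and 51.0 ± 8.60 CPM (adjusted p = 0.0543). Among 61 genes of fatty acid oxidation and peroxisomes, ACSL4 (ENSDARG00000010752) rose by 1.40 (SE 0.21) as the single call in edgeR, while 52 members had fold changes below 0; adjusted over the list alone 1 rose and 2 fell, and DESeq2 called 9 lower and 1 higher. Both lists were highest in wild-type library 3, which carried liver transcripts: gluconeogenesis and amino acid catabolism genes took 0.758% of its counts, against 0.41% and 0.5% in wild-type libraries 1 and 2 and 0.403% to 0.446% in depleted libraries, and fatty acid oxidation genes 0.386%, against 0.242% and 0.228% and 0.195% to 0.215%. Without this library their medians went from -0.58 to -0.21 and from -0.46 to -0.23, and camera with a preset correlation no longer called the first (adjusted p = 0.0767). Among 26 V-ATPase subunits, which acidify endosomes and the tubule lumen, ATP6V1C1 (ENSDARG00000035880) fell by 1.13 (SE 0.14) and ATP6V0C (ENSDARG00000036577) by 1.29 (SE 0.24), and adjusted over the list alone 14 fell. Ionocytes are rich in this pump, both ATP6V1A identifiers are also in the ionocyte list, and that list was lower in the same libraries, with 4 of 27 markers fallen and a median of -0.93. None of 107 nuclear subunits of oxidative phosphorylation passed edgeR's test, over all genes or adjusted over the list alone, while 100 had fold changes below 0 (median -0.32). Of these 107, 13 had an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 1 higher and 2 lower. Camera called these 4 lists lower, with adjusted p of 0.00138, 0.000143, 8.59e-07 and 1.94e-05 in the order given. Over the 6 ways to leave out 1 library 0 to 1 gluconeogenesis genes and 0 to 1 V-ATPase subunits fell, and no fatty acid oxidation gene rose. Each camera call was lost with the estimate, at adjusted p = 0.781, 0.756, 0.356 and 0.781 with an estimated correlation.

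Of 21 tested podocyte markers, 3 rose in edgeR and 11 in DESeq2, and adjusted over the list alone 12 rose. Endothelial markers took 1.85 times their wild-type share in the same depleted libraries, with a list median of 0.77. The podocyte regulator WT1 rose by 1.93 on the log2 scale (SE 0.34, adjusted p = 0.0472), from 10.7 ± 4.83 to 40.9 ± 5.61 CPM (SD, n = 3 each). NPHS1, which encodes nephrin of the slit diaphragm, rose by 1.74 (SE 0.31), from 15.3 ± 2.41 to 51.1 ± 21.0 CPM, and NID1 (ENSDARG00000068710), of basement membrane, rose by 0.86 (SE 0.15). Its slit diaphragm partner nphs2 stood at 11.4 and 36.3 CPM (adjusted p = 0.0544). The podocyte list passed camera at adjusted p = 8.12e-07, against adjusted p = 0.309 with an estimated correlation. Without wild-type library 3 none passed, and 0 to 4 rose over the 6 ways to leave out 1 library.

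Of 62 tested members of the mesenchyme and extracellular matrix list, 10 rose in edgeR's test, and adjusted over the list alone 27 rose and 3 fell; DESeq2 called 26 higher and 1 lower. The metalloproteinase inhibitor TIMP2 (ENSDARG00000075261) rose by 4.42 on the log2 scale (SE 0.39, adjusted p = 0.0105), from 44.2 ± 11.6 to 949.8 ± 392 CPM (SD, n = 3 each). The matricellular gene THBS1 (ENSDARG00000103775) rose by 2.93 (SE 0.34), from 162 ± 59.9 to 1233 ± 178 CPM, and SERPINE1, which encodes the plasminogen activator inhibitor, rose by 3.01 (SE 0.46), from 37.4 ± 12.5 to 302 ± 155 CPM. The other risers were loxl2a, COL12A1 (ENSDARG00000078322), FN1 (ENSDARG00000019815), PDGFRA, TGFB2, MMP14 (ENSDARG00000002235) and CDH11. Endothelial and leukocyte marker shares were 1.85 and 1.92 times those of the wild-type libraries in the same samples. The matrix list passed camera at adjusted p = 8.59e-07, with adjusted p = 0.309 with an estimated correlation. Over the 6 ways to leave out 1 library 1 to 5 members rose, 4 of them without wild-type library 3; TIMP2 passed in each of the 6.

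More collagen genes fell than rose. Of 57 collagen genes, col7a1, col14a1b, col5a3b and col17a1b fell, COL12A1 (ENSDARG00000078322) rose, and 52 did not pass the test; adjusted over the list alone 14 fell and 8 rose. Both col7a1 and col17a1b are also in the epidermis list, whose share of counts was 2.48% in wild-type and 1.39% in depleted libraries. The anchoring fibril gene col7a1 fell by 2.27 on the log2 scale (SE 0.17, adjusted p = 0.0105), from 234 ± 19.8 to 48.4 ± 6.17 CPM, and passed in each of the 6 fits without 1 library. The gene col5a3b fell by 2.27 (SE 0.28), from 753 ± 206 to 157 ± 32.5 CPM. COL12A1 rose by 1.39 (SE 0.21), from 609 ± 44.1 to 1601 ± 267 CPM, a call lost in each of these 6 fits (adjusted p of 0.0693 to 0.111), in which 1 to 8 collagen genes fell and 0 rose. Camera gave adjusted p = 0.0346 for a lower family, and adjusted p = 0.781 with an estimated correlation. With the preset correlation the adjusted p was 0.131, 0.295 and 0.108 without wild-type library 1, wild-type library 3 and depleted library 2.

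Several p53 targets and tubule injury genes rose, among them krt18b, which is also in the ionocyte list. In the same depleted libraries, endothelial and leukocyte markers took 1.85 and 1.92 times their wild-type shares. Of 31 tested p53 targets, 5 rose in edgeR and 14 in DESeq2, and adjusted over the list alone 13 rose; the median log2 fold change was 0.58 and 28 members lay above 0. The p53 ubiquitin ligase gene mdm2 rose by 1.51 on the log2 scale (SE 0.19, adjusted p = 0.0229), from 19.2 ± 2.72 to 54.5 ± 9.55 CPM (SD, n = 3 each), and rps27l rose by 1.73 (SE 0.23), TP53 itself by 1.19 (SE 0.18), PLK2 (ENSDARG00000019130) by 1.1 (SE 0.18) and the cell cycle inhibitor cdkn1a by 1.22 (SE 0.20). Of 39 injury and dedifferentiation genes, CLU, the clusterin gene, rose by 2.95 (SE 0.38), from 36.8 ± 15.7 to 284 ± 70.6 CPM, the tumour necrosis factor receptor genes tnfrsf1b and tnfrsf1a and the keratin krt18b rose in edgeR; adjusted over the list alone 11 rose, and DESeq2 called 11 higher and 2 lower. None of 54 cell cycle genes passed edgeR's test over all genes or adjusted over the list alone, 2 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 1 higher. Camera gave adjusted p = 5.06e-08 for the p53 list and 0.00724 for the injury list, each with adjusted p = 0.356 with an estimated correlation, and 0.64 for the cell cycle list. Without wild-type library 3 no p53 target and 1 injury gene rose, and camera with a preset correlation no longer called the injury list (adjusted p = 0.148), and over the 6 ways to leave out 1 library 0 to 3 p53 targets and 0 to 2 injury genes rose.

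Signalling and early response genes included a pair of SOCS3 genes. SOCS3, a feedback inhibitor of cytokine signalling, rose by 2.27 on the log2 scale (SE 0.26) for ENSDARG00000025428, from 73.4 ± 16.3 to 355 ± 83.2 CPM, and by 2.39 (SE 0.39) for ENSDARG00000026611. They were the only 2 of 30 interferon response genes to pass in edgeR, and adjusted over the list alone 6 rose. Leukocyte markers took 1.92 times their wild-type share in the same depleted libraries. With FOSL2, which rose by 1.93 (SE 0.28), and DUSP6, which rose by 1.37 (SE 0.21), they made up the 4 of 64 immediate early and heat shock genes that rose; adjusted over the list alone 18 rose. Camera gave adjusted p = 0.000386 and 6.04e-08 for these lists, with adjusted p = 0.309 and adjusted p = 0.563 with an estimated correlation. Over the 6 ways to leave out 1 library 0 to 2 interferon response genes and 0 to 3 early response genes rose.

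**Figure D3:**
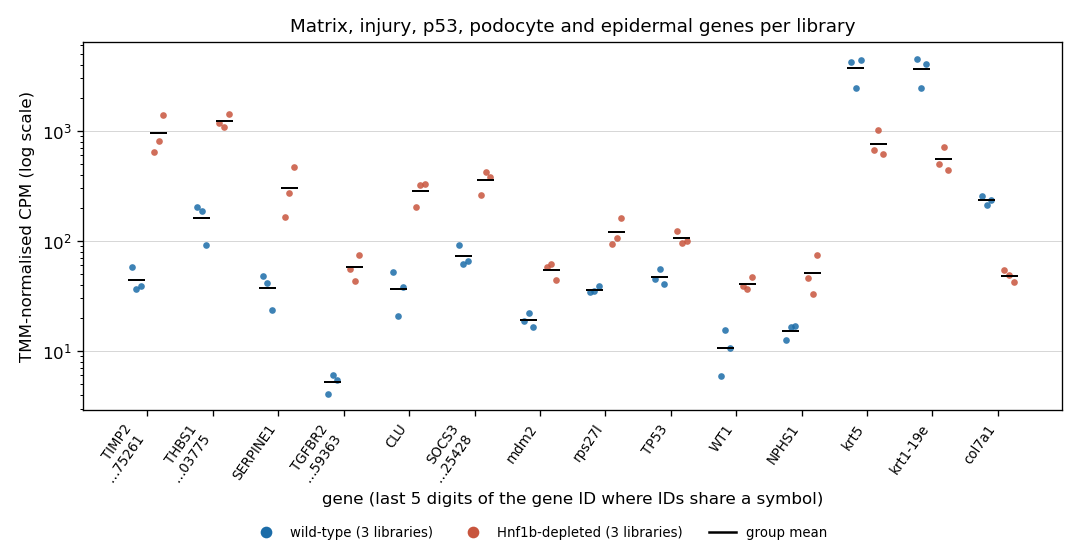
Level of each gene in TMM-normalised CPM on a log axis, with a point for each of the 3 wild-type and 3 Hnf1b-depleted libraries and a bar for the group mean. TIMP2 ENSDARG00000075261 stood at 44.2 CPM in wild-type and 949.8 CPM in depleted libraries, and krt5 at 3707 and 769 CPM.

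Outside the lists, the strongest rises included the metalloproteinase adam8a, by 3.48 on the log2 scale (SE 0.27), the transforming growth factor receptor TGFBR2 (ENSDARG00000059363), by 3.49 (SE 0.27), and the angiopoietin gene ANGPT1, by 3.03 (SE 0.18), from 8.42 ± 1.46 to 68.9 ± 5.77 CPM. Also among the 10 largest rises were the fatty acid synthase gene fasn2, tnfaip2b and tgm2l. The largest falls by rule were epdl2, by 4.78 (SE 0.42), from 31.5 ± 10.1 to 1.14 ± 0.494 CPM, and the aquaporin gene aqp8b, by 3.31 (SE 0.35). The cartilage matrix gene MATN1 fell by 2.92 (SE 0.46), from 1124 ± 336 to 148 ± 85.0 CPM. The calls of adam8a, TGFBR2, ANGPT1 and tnfaip2b held in each of the 6 fits without 1 library, those of epdl2 in 5, of aqp8b and fasn2 in 3, and those of tgm2l and MATN1 in none.

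Cilia, junction and developmental regulator genes gave few calls in edgeR. BICC1 (ENSDARG00000061682), a cystic kidney gene, rose by 0.87 on the log2 scale (SE 0.15), the single member of 56 cilia and cystic kidney genes to pass edgeR's test. Of the 56, 48 lay above 0, adjusted over the list alone 7 rose, and DESeq2 called 11 higher and 0 lower. Of 61 junction and polarity genes, cldn7a rose by 1.27 (SE 0.21) and the apical polarity gene crb2a by 1.70 (SE 0.30) in edgeR; adjusted over the list alone 5 rose and 1 fell, and DESeq2 called 11 higher and 3 lower. Of 35 claudins, CLDN11 (ENSDARG00000020031), CLDN5 (ENSDARG00000014059) and cldn7a rose in edgeR. Adjusted over the list alone 5 rose and 1 fell, and DESeq2 called 6 higher and 3 lower. CLDN5 is also in the endothelial list, which took 1.85 times its wild-type share in the depleted libraries. None of 35 nephron transcription factors and none of 41 Notch pathway genes passed edgeR's test over all genes or adjusted over the list alone; 12 and 10 had an unadjusted p under 0.05. Limma-voom called 0 of them, while DESeq2 called 4 nephron transcription factors higher and 4 lower, and 4 Notch genes higher and 2 lower. In each of the 6 fits without 1 library 0 cilia, junction and claudin genes rose, so the calls named here rest on all 6 libraries. Camera called the cilia list higher at adjusted p = 9.63e-08, and adjusted p = 0.356 with an estimated correlation. It called none of the other 4 lists, at adjusted p of 0.332 for junctions, 0.611 for claudins, 0.698 for transcription factors and 0.883 for Notch. Fry's mixed test, for changes in either direction, passed the cilia, junction and claudin lists (adjusted p = 0.00167, 0.00021 and 0.000543). It gave 0.0541 for transcription factors and 0.0595 for Notch.

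Genes reported as HNF1B targets in mammals changed in both directions. The list does not record whether HNF1B raises or lowers each gene, so these directions were not compared with reported ones. Of 58 tested, 4 fell (CUBN, cltrn, SLC3A1 and SLC7A9), 3 rose (a pair of SOCS3 genes and BICC1 ENSDARG00000061682) and 51 did not pass the test; adjusted over the list alone 11 fell and 9 rose. Over the 6 ways to leave out 1 library 0 to 3 fell and 0 to 2 rose, with 2 and 2 without wild-type library 3, and BICC1 passed in none of the 6. Camera, which tests a common shift of a list, did not call it (adjusted p = 0.287), while fry's mixed test did (adjusted p = 0.000543). Among its 60 genes, 46 also stood in another fixed list.

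**Figure D4:**
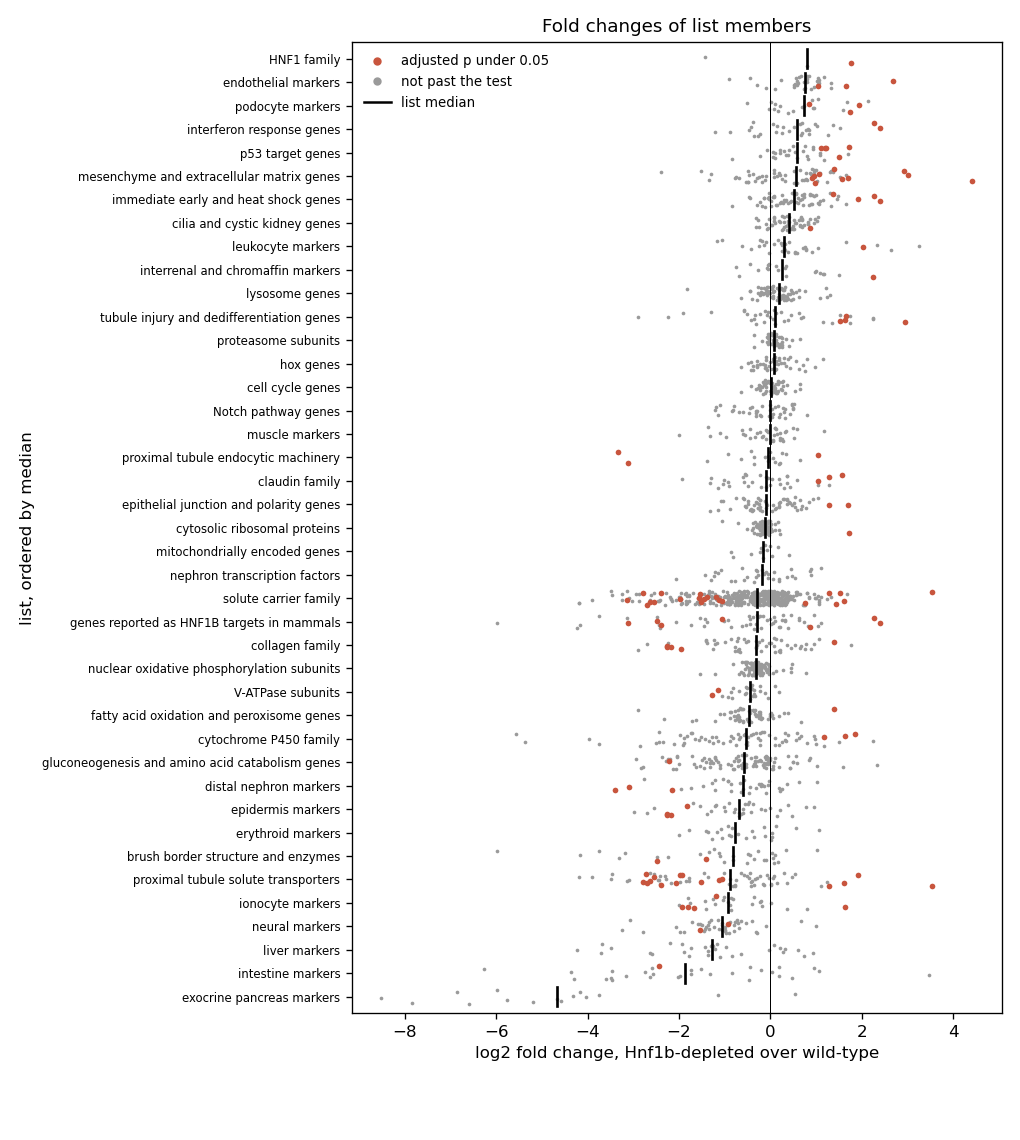
Log2 fold change, Hnf1b-depleted over wild-type, of each tested member of the 41 lists and families, ordered by median from lowest to highest. Red points passed an adjusted p of 0.05 in edgeR's test, grey points did not, and black bars are list medians, which were -0.89 for proximal tubule transporters and 0.75 for podocyte markers.

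Some markers of other cell types changed as well. The keratin gene krt5 fell by 2.27 on the log2 scale (SE 0.34), from 3707 ± 1109 to 769 ± 218 CPM. With col7a1, col17a1b and the mucin gene muc5.2 it made up the 4 of 37 epidermis markers that fell in edgeR, and adjusted over the list alone 18 fell and 2 rose; DESeq2 called 18 lower and 1 higher. The keratin gene krt1-19e, whose symbol matched no name of the list, fell by 2.73 (SE 0.33), from 3668 ± 1070 to 552 ± 143 CPM. Of the 40 names fixed for epidermis 2 found no match, and other names of these genes were not searched. Of 27 ionocyte markers the transcription factors foxi3b and GCM2, slc12a10.2 and ATP1B1 (ENSDARG00000076833) fell and krt18b rose; adjusted over the list alone 14 fell and 2 rose. Of 46 neural markers STMN1 (ENSDARG00000033655) and SOX10 fell in edgeR and 22 in DESeq2, and adjusted over the list alone 25 fell. Of 35 endothelial markers the scavenger and lymphatic receptor genes lyve1a, by 2.68 (SE 0.25), and stab1, by 1.65 (SE 0.21), and CLDN5 (ENSDARG00000014059) rose in edgeR and 18 in DESeq2; adjusted over the list alone 20 rose and 1 fell. The proteoglycan srgn was the single leukocyte marker of 36 to rise and STAR, of steroid synthesis, the single interrenal and chromaffin marker of 20 in edgeR, each also adjusted over the list alone. Camera gave adjusted p = 1.48e-06 for epidermis, 6.71e-06 for ionocytes, 3.53e-11 for neural markers, 1.4e-10 for endothelium, 0.00182 for leukocytes and 0.0376 for the interrenal list. Each of these calls was lost, at adjusted p = 0.309, 0.309, 0.356, 0.356, 0.629 and 0.638 with an estimated correlation. With the preset correlation the interrenal call was also lost without wild-type library 1, wild-type library 3 or depleted library 1 (adjusted p = 0.0839, 0.0506 and 0.103). Without 1 library, 1 to 5 epidermis markers, 0 to 4 ionocyte markers, 0 to 1 markers in each of the neural, leukocyte and interrenal lists, and 0 to 3 endothelial markers passed in that direction.

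Digestive, muscle and blood markers gave 1 call. The intestinal mucin muc13b fell by 2.43 on the log2 scale (SE 0.44), the only one of 30 intestine markers to pass in edgeR over all genes, and passed in 1 of the 6 fits without 1 library. None of 38 muscle markers, 31 liver markers, 15 exocrine pancreas markers, 24 erythroid markers and 13 mitochondrially encoded genes passed edgeR's test over all genes; 4, 5, 13, 9 and 0 of them had an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 3, 2, 1, 4 and 0 lower. Adjusted over the list alone, 12 exocrine pancreas markers fell and 1 rose, 4 erythroid markers fell, 1 intestine marker fell and 1 rose, and no other of these lists had a call. The trypsin gene prss1 stood at 282 ± 474 CPM in wild-type libraries, of which 829 CPM in library 3, and at 4.47 ± 3.17 in depleted ones. Camera called the pancreas (adjusted p = 0.00525) and erythroid lists (0.00391) lower, both lost at adjusted p = 0.781 and adjusted p = 0.563 with an estimated correlation, the erythroid call also without wild-type library 1 (adjusted p = 0.057 with the preset correlation). Its adjusted p was 0.0529 for intestine, 0.315 for liver, 0.883 for muscle and 0.718 for mitochondrial genes. When wild-type library 3, which had the lowest muscle share and most of the pancreas transcripts, was left out, camera called the muscle list lower with a preset correlation (adjusted p = 0.00163, median -0.33 in place of -0.015), and the pancreas median was -0.92 in place of -4.66.

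Few members of the remaining families passed. Of 72 cytochrome P450 genes CYP27C1, cyp1c1 and cyp1c2 rose, by 1.63, 1.17 and 1.84 on the log2 scale (SE 0.18, 0.15 and 0.29) in edgeR; adjusted over the list alone 3 rose and 4 fell. DESeq2 called 6 of the family higher and 12 lower, and the family median was -0.54, or 0.007 over the 74 genes tested without wild-type library 3. Of 80 cytosolic ribosomal protein genes only rps27l, which is also in the p53 list, rose in edgeR's test, over all genes and adjusted over the list alone. Over the 6 ways to leave out 1 library 0 to 2 cytochrome P450 genes and 0 ribosomal protein genes rose. None of 46 proteasome, 48 hox and 75 lysosome genes passed it, over all genes or adjusted over the list alone; 0, 3 and 10 had an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 1 hox and 5 lysosome genes higher. Camera called the lysosome list higher (adjusted p = 0.0089), and at adjusted p = 0.781 with an estimated correlation did not, nor with the preset correlation without wild-type library 2 (0.219) or depleted library 3 (0.0771), and called none of the other 4, at 0.106, 0.0529, 0.0923 and 0.0616 in the order given. Of these families, fry's mixed test passed only the cytochrome P450 genes (adjusted p = 0.0176).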

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

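The fit with muscle level was chosen after the result was seen. The 515 calls kept their sign in every fit that tested them, which their groups without overlap made close to certain, so this says little about stability. Against 515 genes changed (337 higher, 178 lower, 65.4% higher; 444 over 2-fold), DESeq2 called 2767 (1414 higher, 1353 lower, 51.1% higher; 1742 over 2-fold). The muscle covariate gave 921 (499 higher, 422 lower, 54.2% higher; 796 over 2-fold), and a test against a log2 change of 0.5 gave 130; the cause was not tested beyond the stricter null of the last. With 1 library left out, which lowers the number of samples, the counts were 12 to 258 changed (63, 258 and 171 without wild-type library 1, 2 and 3, and 22, 34 and 12 without depleted library 1, 2 and 3), 11 to 137 higher, 1 to 121 lower and 12 to 255 over 2-fold, and 53.1% to 91.7% of calls were higher. The other 7 settings gave 447 to 587 genes. The solute carrier odds ratio of 5.38 went to 0 without depleted library 1, 2 or 3, each leaving few lower genes, and its range with 1 library left out was 0 to 13.6. Of 40 lists 25 passed camera, 0 with an estimated correlation, 8 by fry and 25 by its mixed form. Without 1 library 22 to 29 of the 40 passed camera, among them 21 to 24 of the 25 that passed it with all libraries. All 35 counts of list members above 0 dropped by more than 1.5 times without at least 1 library, and 30 rose as much under DESeq2. Of 3000 values of named genes under alternatives, 2404 kept their side of the threshold, 479 lost a call, 93 gained one and 24 reversed; 5 had no adjusted p in DESeq2. The reversals were of log2 fold changes that had not passed the test. Without dominant genes in the scaling eef1a1l1 went from -0.02 to 0.002 and hsp70.3 from -0.02 to 0.001; with library totals only c5 went from 0.04 to -0.018, and with limma-voom c8a from -0.32 to 0.70. With 1 library left out the ranges were -0.162 to 0.115 for eef1a1l1, -0.202 to 0.096 for hsp70.3, -0.746 to 0.082 for atp2a1, -0.778 to 0.127 for myhz1.1, -0.021 to 0.128 for eef2b, -0.728 to 0.006 for MT-ND3, -0.094 to 0.741 for actc1b, -0.053 to 0.285 for actb2, -0.066 to 0.27 for HSP90AB1, -0.492 to 1.789 for c5, -0.875 to 1.012 for c8a and -2.0 to 0.011 for c9; the cause was not tested. No paired analysis was possible because the groups share no replicate numbers in the labels. Depth left 24278 of 30627 genes with enough counts to test and was not varied. Of simulated changes of 1 on the log2 scale 9.2% were recovered, and 4% with 2 libraries against 3.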

Other observations

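Genes in this section were picked after their values were seen, except c6.2, prl, gcga, STAR, krt18b and krt5, which the fixed rule named. The complement genes c6.2, c6.1 and c7a rose in the depleted libraries: c6.2 by 2.99 on the log2 scale (SE 0.29), from 53.1 ± 15.7 to 422 ± 101 CPM (SD, n = 3 each), c6.1 by 2.67 (SE 0.19) and c7a by 2.59 (SE 0.31), from 45.5 ± 12.6 to 274 ± 84.4 CPM, with edgeR adjusted p of 0.0142, 0.0105 and 0.0207. The other genes named for components of this pathway step, c5, c7b, c8a, c8b, c8g and c9, did not pass, with adjusted p from 0.267 (c8g) to 0.988 (c5). The adrenomedullin gene ADM (ENSDARG00000015263) rose by 2.55 (SE 0.17), from 21.6 ± 3.76 to 127 ± 8.57 CPM, and the prostaglandin E synthase gene PTGES by 2.55 (SE 0.22), both called in each of the 6 fits without 1 library. The pituitary hormone gene prl rose by 3.90 (SE 0.48), from 2.37 ± 1.35 to 35.6 ± 10.6 CPM, and the glucagon gene gcga stood at 8.17 ± 8.48 and 90.2 ± 21.1 CPM (adjusted p = 0.109). The steroid synthesis gene STAR rose by 2.25 (SE 0.38). Of these 6 fits c6.1 passed in all, c6.2 in 3, prl in 2, and c7a and STAR in 1 each.

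The ammonia channel gene RHBG fell by 2.1 on the log2 scale (SE 0.34), from 267 ± 108 to 62.4 ± 15.7 CPM, and passed in 2 of the 6 fits without 1 library. The simple epithelial keratins krt8 and krt18a.1 stood at 664 ± 106 and 449 ± 140 CPM in wild-type libraries and 1698 ± 529 and 1503 ± 563 in depleted ones, each with an adjusted p of 0.0597, while krt18b rose by 1.64 (SE 0.26), a call lost in each of the 6 fits. The basal keratin krt5 fell by 2.27, and col17a1a of hemidesmosomes stood at 644 ± 252 and 98.5 ± 58.6 CPM (adjusted p = 0.0522).

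All tests in the next paragraphs were chosen after the result was seen, except those on tubule genes without transport function and on other splits of the libraries. Standard errors of list medians there are taken across genes as if these were independent. They leave out the spread between libraries and are too small where genes of a list move together. The real split of the 6 libraries called 515 genes, the highest of the other 9 called 0, and 1 of the 10 splits gave as many; with 10 splits the share cannot fall below 0.1.

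The list of proximal tubule transporters had a median of -0.89 on the log2 scale over 71 genes. A lower share of tubule cells, as the only difference between collections, would raise markers of all other cell types alike. The endothelial median lay above the epidermis median by 1.46 (SE 0.24), so the mix of other tissues differed as well. These lists stand for tissues outside the tubule, so the test cannot show whether the share of tubule cells was lower. The bound set beforehand for CDH17, PAX8 and the PAX2 and LHX1 genes was 0.5 times the median of the 12 transporters that fell. The median of these tubule genes, -0.41 (SE 0.27, 6 genes), lay above it by more than its error, the outcome set down as against fewer tubule cells. That bound rests on genes picked because they fell, so it was replaced by 0.5 times the list median. The value of -0.41 lies within its error of this second bound. CDH17 stood at -1.08 (278 and 131 CPM, edgeR adjusted p = 0.134), lhx1a at -0.50, lhx1b at -0.32, PAX8 at 0.05 and the PAX2 identifiers at -0.58 and 0.45. Without wild-type library 3, which carried gut, liver and pancreas transcripts, the list median was -0.34 (SE 0.20), also within its error of the bound, so how far this tissue accounts for the shift cannot be told, though 6 members fell in that fit. Loss of Hnf1b, the difference the design names, stays open and untested beside that tissue, a shortfall of tubule cells and morpholino injection in itself.

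The p53 list had a median of 0.58. A stronger heat shock response to the digestion in depleted collections would raise heat shock genes with it. These had a median of 0.11 (SE 0.11, 20 genes), below 0.5 times the p53 median by more than that error. The immediate early and heat shock list had an estimated inter-gene correlation of 0.411, so the error is too small. The values give no sign of such a response but do not exclude it. Immediate early genes outside the p53 list had a median of 0.65 (SE 0.13, 43 genes), with all libraries as high as the p53 list. An early response to dissociation would need this, and this explanation stays open. Without wild-type library 3 the whole immediate early and heat shock list had a median of 0.32 in place of 0.52, and the p53 list 0.49 in place of 0.58. Injection of a morpholino in itself, which may induce p53 targets, cannot be told apart from loss of Hnf1b, since 0 libraries are labelled as control morpholino. The same holds for every other difference between the groups.

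The epidermis list had a median of -0.69. Less of every adhering tissue would lower the endothelial and leukocyte lists, whose medians were 0.77 and 0.31; the muscle median was -0.015, or -0.33 without wild-type library 3, and the neural and ionocyte medians were -1.05 and -0.93. Less epidermis carried over stays open, since superficial markers had a median of -0.60 (SE 0.19, 11 genes), as this would need. The basal gene TP63 stood at -0.69 (adjusted p = 0.0639), near the superficial median, while krt5, col7a1 and col17a1b fell by 2.27, 2.27 and 2.17. That further fall was seen in genes picked because they fell, so it was not tested.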
